A study of Mus musculus with 32 samples.

How the data were processed

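The series holds RNA sequencing of T cells sorted from liver and spleen of male Foxp3-GFP C57BL/6 mice that were untreated or given CCl4. Per the labels, regulatory T cells were sorted as TCRb+CD4+Foxp3+ and conventional CD4 T cells as TCRb+CD4+Foxp3-, and each of the 4 populations has 3 control and 5 CCl4 libraries, 32 in all. The labels do not say that the libraries of a group come from separate animals, so the p-values measure the spread between samples. A diet named in the treatment protocol belongs to none of these samples.

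Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.19 and assigned to transcripts with kallisto 0.44.0, with GRCm38.p6 named as the genome build and DESeq2 named without a version. The annotation release and the strand setting are not given in the sources used here. Each deposited table holds, per the file headers, the estimated count of each transcript as kallisto gave it to the authors, which is not a whole number. It also holds the TPM, which the authors computed with division by effective length. Every table lists 118489 transcripts. Estimated counts summed to between 24513124 and 75292019 per library.

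Estimated counts were summed to genes with the transcript names of a GENCODE M21 reference. This matched 98.5% of the transcripts to 35968 genes; the 1761 unmatched transcripts held between 0.684% and 0.823% of a library's counts and were left out. Gene sums were rounded to whole numbers for edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the 8 groups, leaving 17159, and TMM factors ran from 0.923 to 1.065. A single quasi-likelihood fit of the 8 groups left 24 residual degrees of freedom, with a common biological coefficient of variation of 0.285. CPM are TMM-normalized. Standard errors (SE) are approximate, the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic, and are unreliable for genes near the floor. Adjusted p are Benjamini-Hochberg values over all genes tested, and a gene is called at an adjusted p under 0.05. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

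The comparisons were CCl4 against control in each population, liver against spleen in Treg and in Tconv, Treg against Tconv in liver and in spleen (each averaged over both treatments), and 5 differences of effects. For Areg the CPM were also compared by two-sided exact permutation tests within each population. Lists of genes were tested with camera from limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 28 lists of a comparison. Of these, 18 are programmes of T cells and metabolism and 10 are markers of other cells that the gates or tissues could bring. The lists share members with each other (Ebi3, Cd160, Il2rb, Gzma and Prf1, for example), and T cells themselves express many of the NKT-like, NK and dendritic markers. A list's median log2 fold change, mean and camera direction differed in sign for 20 lists over the 8 main comparisons, 0 of them called, and for 25 lists over the 5 differences of effects, of which 2, both of hepatocyte markers, were called.

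In each main comparison the text names the 8 largest rises and the 8 largest falls among called genes with a mean of at least 5 CPM whose library values did not overlap between the groups. Fewer are named where fewer met these conditions. For contrasts averaged over treatments, the values had to be apart within control and within CCl4 libraries. Predicted genes, pseudogenes, ribosomal and mitochondrial genes and immunoglobulin or receptor segments were left out. Areg, Foxp3, Il1rl1, Klrg1, Gata3, Il10, Ctla4, Ikzf2, Cxcr3 and Egfr are named in every main comparison, with the list members of smallest adjusted p. A further gene that the rule names is not reported here, though it counts in the tests and totals. For differences of effects the 5 genes of smallest adjusted p and Areg are named. Fos, the pancreatic enzymes, Ccr7, Klf2 and the genes of the closing observations were chosen after their values were seen. The invariant receptor segments belong to a test that was fixed before its result was seen.

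Alternatives were DESeq2 size factors in edgeR, no filter on low counts, a mean of at least 5 CPM, a fit of the libraries compared alone, length offsets, limma-voom, DESeq2 1.42.0, a block by sample number, leaving out each library, an estimated correlation for camera, and fry. Levels of Areg were also taken as deposited TPM and as CPM without TMM, and the agreement between populations over genes of at least 5 CPM. Comparisons, lists, the rule for named genes and these alternatives were fixed before the data were examined. Leaving out the 4 spleen control libraries numbered 2 and 3 was added after seeing the data.

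The steps were tested on simulated data with the group sizes and spread of these libraries. Genes were drawn independently of each other, and the changed genes were taken from those with a mean of at least 5 CPM. Of genes changed 1.5-fold, 62.7% were called in liver Treg, 53.7% in liver Tconv, 65.7% in spleen Treg and 56.7% in spleen Tconv; of those changed 2-fold, 85.1%, 91.0%, 88.1% and 95.5%. Between 6 and 9 of 16959 unchanged genes and 0 of 27 unchanged lists were called by edgeR and camera. As the simulated genes were independent, this does not show how camera treats lists of correlated genes.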

Results

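Regulatory T cells (Treg, sorted as TCRb+CD4+Foxp3+) and conventional CD4 T cells (Tconv, TCRb+CD4+Foxp3-) of liver and spleen were compared between control mice and mice given carbon tetrachloride (CCl4). Each of the 4 populations had 3 control and 5 CCl4 libraries. On the principal components of log2 CPM the 32 libraries grouped by tissue and cell type, with 30.8% of the variance on the first component and 21.4% on the second. Foxp3, which defined the sort gate and so checks the labels, averaged 1021 ± 67.3 CPM (mean ± SD, n = 8) in liver Treg and 1059.7 ± 86.5 in spleen Treg, against 1.46 ± 0.846 and 2.22 ± 0.689 in liver and spleen Tconv.

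**Figure D1:**
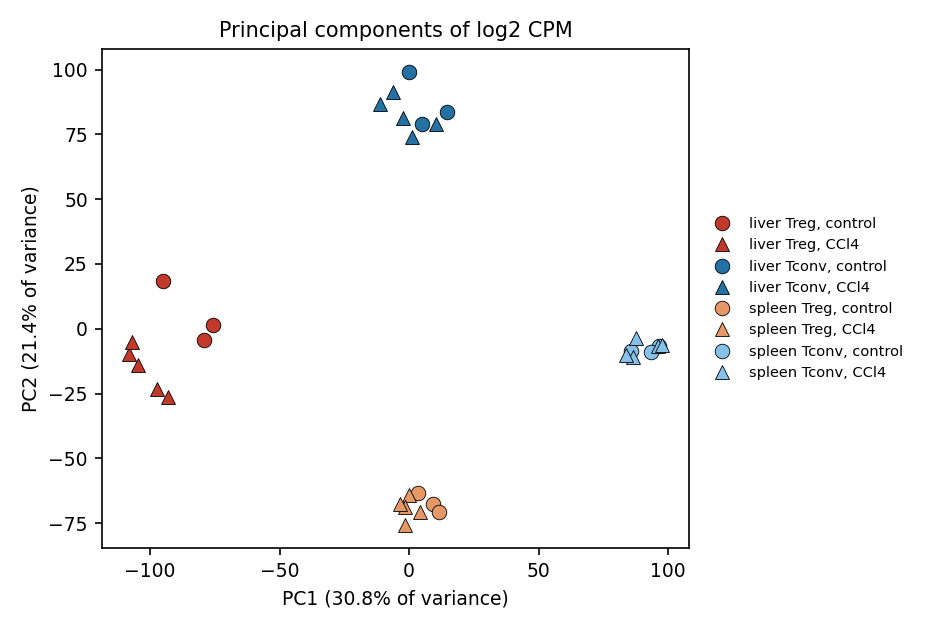
Principal components of log2 CPM of the 32 libraries: the first component (30.8% of the variance) on the x axis and the second (21.4%) on the y axis, in arbitrary units. Each point is 1 library, circles are the 3 control and triangles the 5 CCl4 libraries of a population, and the 4 populations fall in 4 separate groups.

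Areg, which encodes the epidermal growth factor receptor ligand amphiregulin named in the series title, was far more abundant in liver Treg than in the other populations. It averaged 72.2 ± 22.2 CPM in the control and 132 ± 24.7 CPM in the CCl4 libraries of liver Treg (n = 3 and 5; 116 ± 35.8 and 204 ± 37.2 TPM). The corresponding levels were 8.74 ± 2.9 and 14.5 ± 3.12 CPM in liver Tconv, 2.95 ± 2.42 and 8.45 ± 1.18 in spleen Treg, and 0.213 ± 0.281 and 0.57 ± 0.373 in spleen Tconv. Averaged over both treatments, Areg was higher in liver than in spleen in Treg (log2 fold change 4.31, SE 0.30, adjusted p = 5.54e-13) and in Tconv (4.96, SE 0.36, adjusted p = 3.11e-12), a difference between the cell types that was not called (-0.65, SE 0.47, adjusted p = 0.379). It was higher in liver Treg than in liver Tconv (3.11, SE 0.27, adjusted p = 8.12e-11). After CCl4 the edgeR test did not call Areg in liver Treg (log2 fold change 0.87, SE 0.36, adjusted p = 0.103), spleen Treg (1.56, SE 0.41, adjusted p = 0.0503), liver Tconv (0.71, SE 0.37, adjusted p = 0.417) or spleen Tconv (1.22, SE 0.71, adjusted p = 0.444). All 5 CCl4 libraries lay above the highest control in liver Treg and in spleen Treg, 4 in liver Tconv and 2 in spleen Tconv. Two-sided exact permutation tests of the CPM gave p = 0.0179 in both Treg populations, the smallest that the 56 splits allow, 0.0536 in liver Tconv and 0.232 in spleen Tconv (0.0358, 0.0715 and 0.232 after adjustment over the 4 tests). The edgeR fit takes a gene's spread from all 8 groups, so a missing call does not rest on the spread within liver Treg alone. The edgeR call depended on the settings: over 17 alternatives the adjusted p ranged from 0.000746 to 0.351 in liver Treg, with 3 past the threshold. It ranged from 0.00177 to 0.836 in spleen Treg, with 5 past it. In spleen the rise rests on controls 2 and 3, which had low Fos: Areg was 5.71 CPM in spleen Treg control 1 and 1.89 and 1.24 in those controls. Without them, a choice made after seeing the data, the log2 fold change was 0.57 in spleen Treg (adjusted p = 0.836) and 0.05 in spleen Tconv (adjusted p = 1). Egfr, the gene for the receptor, was near the detection floor, at 1.46 ± 0.72 and 1.39 ± 0.394 CPM in control and CCl4 liver Treg.

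**Figure D2:**
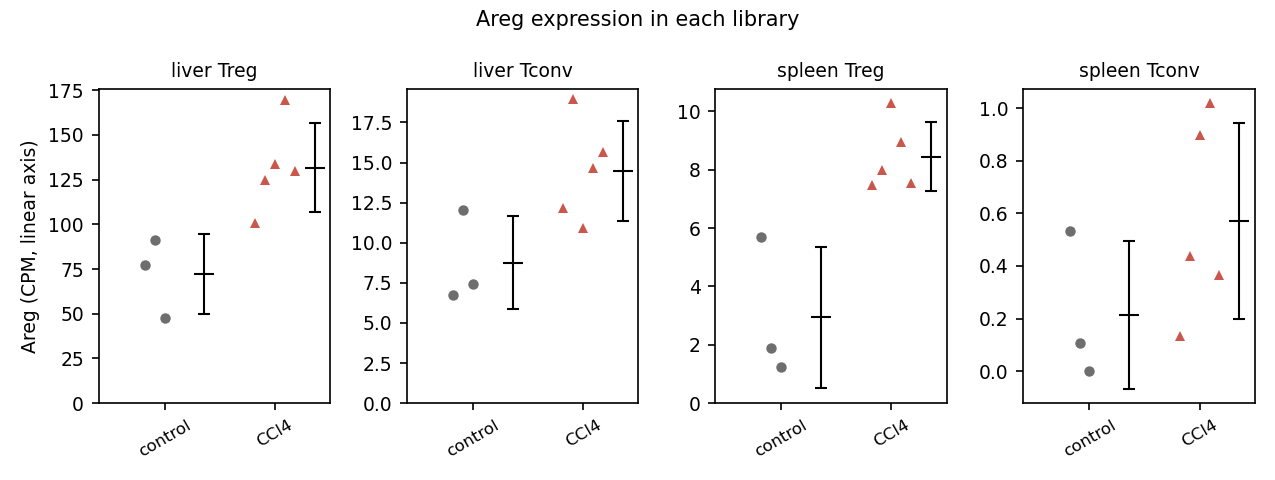
Areg expression in CPM (y axis, linear, with its own range in each of the 4 panels) in each library of the 4 sorted populations. Circles are the 3 control and triangles the 5 CCl4 libraries, and the bars give mean ± SD. Liver Treg lay at 72.2 ± 22.2 and 132 ± 24.7 CPM, with every CCl4 library above every control there and in spleen Treg.

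CCl4 changed far more genes in liver Treg than in any other population. There 13 of 14 naive and lymphoid recirculation genes fell and 9 of 18 genes of the tissue Treg and repair list rose, Il10 and Areg not being called. The call of the tissue Treg list was lost with an estimated correlation (adjusted p = 0.0886). Tcf7, the transcription factor of naive and memory-like T cells, went from 235 ± 9.66 to 77.0 ± 8.01 CPM (mean ± SD, n = 3 and 5; log2 fold change -1.61, SE 0.09, adjusted p = 1.73e-13). Gata3, a transcription factor shared by type 2 helper cells and tissue Treg, rose from 301 ± 30.6 to 864 ± 144 CPM (1.52, SE 0.12, adjusted p = 4.81e-10). Of 17159 genes tested, 1295 were higher and 1260 lower at an adjusted p of 0.05, 368 and 337 of them by more than 2-fold. Library values did not overlap between control and CCl4 for 19.1% of the genes tested, where chance gives 3.57%.

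In the naive and lymphoid recirculation list, 13 of 14 measured members fell in liver Treg, none rose, and 1 was not called (also 13 when adjusted over the list alone; camera adjusted p = 1.03e-22, and 0.0193 with an estimated correlation). Besides Tcf7 these included Satb1, a chromatin organiser (-2.01), S1pr1, the receptor for exit from lymphoid organs (-1.32), and Ly6c1 (-2.30). In the tissue Treg and repair list 9 of 18 members rose, none fell and 9 were not called (12 higher and 1 lower when adjusted over the list alone; camera adjusted p = 6.28e-07, adjusted p = 0.0886 with an estimated correlation). Id2 rose by 1.80, the chemokine receptor gene Ccr8 by 1.71, the nuclear receptor gene Pparg by 2.59, Klrg1 by 1.61 (SE 0.45, adjusted p = 0.013) and Il1rl1, which encodes an alarmin receptor, by 0.98 (SE 0.28, adjusted p = 0.0145). Il10 averaged 221 ± 40.5 against 72.9 ± 12.2 CPM but was not called (1.60, SE 0.62, adjusted p = 0.0823). The fit takes its spread from all 8 groups, among them CCl4 groups of Tconv with 1 library far from the rest. The Th2 list rose with 3 of 7 members higher and none lower (4 when adjusted over the list alone; camera adjusted p = 0.00014, and 0.0374 with an estimated correlation). Its 3 members were Cyp11a1, the enzyme that starts steroid synthesis (56.5 ± 12.5 against 3.36 ± 1.55 CPM; 4.06, SE 0.36, adjusted p = 2.43e-09), the eosinophil cytokine gene Il5 (3.55, SE 0.66, adjusted p = 0.000313) and the alarmin receptor gene Il17rb (1.67, adjusted p = 0.00123).

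The Treg identity genes did not move as a list: 2 of 14 rose and 1 fell (4 and 1 when adjusted over the list alone; camera adjusted p = 0.208). Foxp3 (0.11, adjusted p = 0.7), Ikzf2 (0.13, adjusted p = 0.681) and Ctla4 (0.17, adjusted p = 0.575) were not called, nor was the chemokine receptor gene Cxcr3 (-0.09, adjusted p = 0.828). Tnfrsf18 (0.55) and Entpd1 (0.89) rose and the orphan receptor gene Gpr83 fell (-1.71). In the activation and coinhibition list 7 of 14 rose, none fell (8 and 1 when adjusted over the list alone; camera adjusted p = 0.000311, adjusted p = 0.332 with an estimated correlation). Among them were Cd38 (1.76), Cd44 (0.87) and the costimulatory receptor genes Tnfrsf9 (0.90) and Tnfrsf4 (0.81). Interferon response genes fell, 12 of 21 lower and 1 higher (15 and 1 when adjusted over the list alone; camera adjusted p = 1.37e-10, and 0.0374 with an estimated correlation), with Usp18 at -1.17, Oas3 at -1.12 and the transcription factor Irf7 at -0.94. Of the follicular helper genes 3 of 9 fell, including Slamf6 (-1.02) and Sh2d1a (-0.88), and 2 rose (5 and 2 when adjusted over the list alone; camera adjusted p = 0.0451, adjusted p = 0.332 with an estimated correlation).

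Some metabolic lists moved in liver Treg as well. Of 19 cholesterol synthesis genes 8 fell and none rose (10 when adjusted over the list alone; camera adjusted p = 3.23e-05, adjusted p = 0.162 with an estimated correlation), with mevalonate kinase Mvk at -1.31 and Fdps at -0.72. Oxidative phosphorylation had 5 of 18 higher and none lower (6 when adjusted over the list alone; camera adjusted p = 0.00339, adjusted p = 0.543 with an estimated correlation), with Ndufv2 at 0.52 and Sdha at 0.38. Glycolysis had 4 of 16 higher and 1 lower (5 and 1 when adjusted over the list alone; camera adjusted p = 0.0263, adjusted p = 0.55 with an estimated correlation). The fatty acid handling list had 5 of 19 higher and 1 lower and missed the threshold (6 and 1 when adjusted over the list alone; camera adjusted p = 0.0554). The lipid droplet coat gene Plin2 rose by 2.20 and the acyl-CoA dehydrogenases Acadvl and Acadl by 0.75 and 0.58. Camera did not call the chemokine receptor and integrin list (adjusted p = 0.844; 4 of 22 higher, 3 lower), Th1 and cytotoxic (0.837; 0 and 1 of 16) or EGFR ligands and growth factors (0.689; 1 and 0 of 18, the 1 being Fgl2 at 1.88). Th17 was not called either (0.761; 2 and 1 of 12, with a median log2 fold change of -0.18 and an upward camera direction), nor were cell cycle (0.157; 1 and 3 of 24), immediate early and heat shock (0.985; 0 and 1 of 18) and NF-kB (0.844; 3 and 1 of 15).

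The 8 largest rises named by the rule in liver Treg were Cyp11a1, Il5, the fetal serum protein gene Afp (3.24), the cytokine receptor chain Csf2rb (3.23), Tmem273 (3.15), the potassium channel gene Kcna4 (3.06), the neutrophil chemokine gene Cxcl3 (3.02) and Nckap5 (3.00). The 8 largest falls were Mup1 (-3.13), Arhgap20 (-2.68), the sodium pump subunit gene Atp1b1 (-2.58), Gabrr2 (-2.47), Ly6c1 (-2.30), Nsg2 (-2.25), the chemokine receptor gene Ccr10 (-2.19) and Serpina3f (-2.12). Mup1 is a hepatocyte product with near-identical copies, so reads cannot be assigned to it with certainty. Among markers of other cells, the hepatocyte list was lower by camera with no member called (0 of 16; adjusted p = 0.00339, adjusted p = 0.55 with an estimated correlation). Alb stood at 100.5 CPM in CCl4 library 3 and between 11.6 and 27.6 in the controls. No other marker list was called: NKT-like 1 of 15 higher, stellate 1 of 11 higher, endothelial 1 higher and 3 lower of 11, myeloid 1 and 1 of 16, and dendritic 1 and 1 of 10. The test called none of the CD8 T (2), NK (5), B cell (14) and erythroid (8) markers. Control library 1 also carried pancreatic enzyme transcripts (Amy2a5 at 422.5 and Cela2a at 232.8 CPM). Without it 1779 genes were called in place of 2555.

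**Figure D3:**
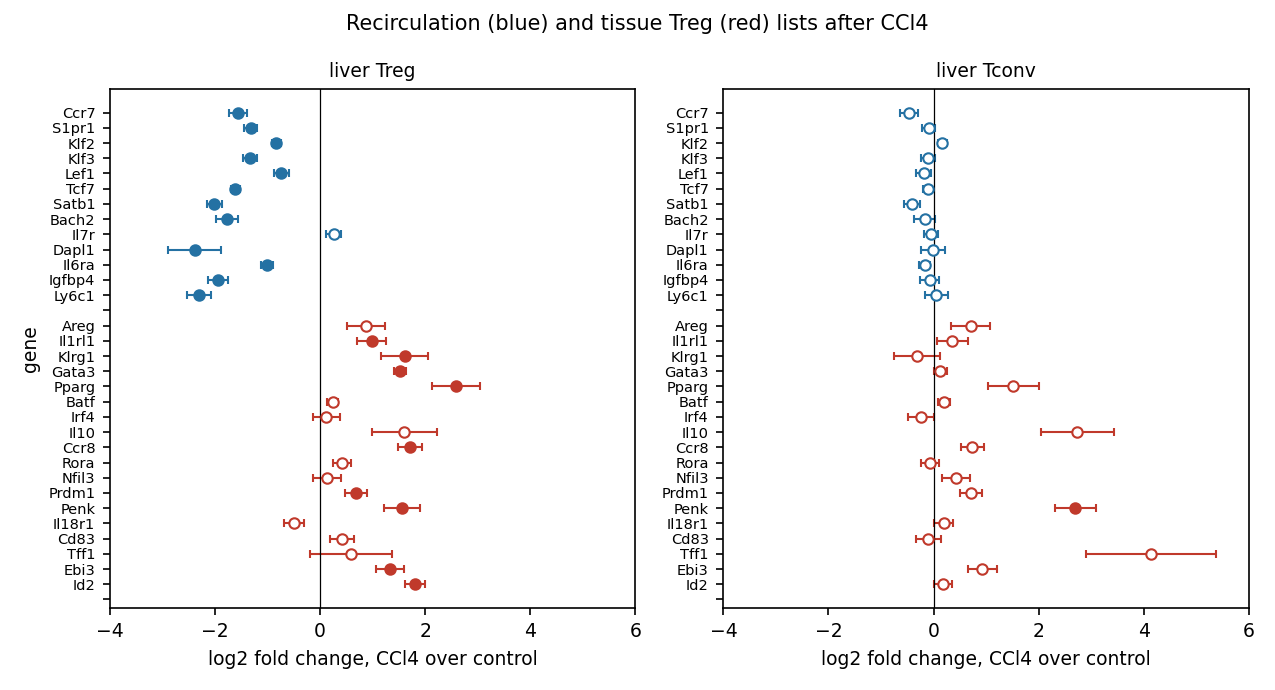
Log2 fold change of CCl4 over control (x axis) for 13 genes of the naive and lymphoid recirculation list (blue) and the 18 of the tissue Treg and repair list (red) in liver Treg (left) and liver Tconv (right). Points are edgeR estimates from 5 CCl4 and 3 control libraries, bars are ± 1 SE, and filled points passed an adjusted p of 0.05. Of the recirculation genes drawn 12 fell in liver Treg and 0 passed in liver Tconv.

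In liver Tconv, edgeR called 56 genes after CCl4, a count that depends on the method (7 in a fit of these libraries alone, 156 in limma-voom and 273 in DESeq2). The opioid precursor gene Penk rose from 5.43 ± 0.441 to 35.6 ± 19.5 CPM (n = 3 and 5; log2 fold change 2.70, SE 0.39, adjusted p = 0.00256). Spry1, an inhibitor of receptor tyrosine kinase signalling, rose from 54.6 ± 4.9 to 175 ± 58.3 CPM (1.69, SE 0.31, adjusted p = 0.0329). Zbtb16, the transcription factor of innate-like T cells, fell from 25.1 ± 10.7 to 3.79 ± 1.82 CPM (-2.73, SE 0.61, adjusted p = 0.0408). In all 25 genes were higher and 31 lower, and the library values of 6.6% of genes did not overlap (3.57% by chance). The other named rises were Ctrc, a pancreatic protease gene (1.72), Creb5 (1.60), Pla2g15 (1.22), Fam214b (1.00), Hist1h4n (0.94) and Cdk6 (0.74). Major urinary protein genes made by hepatocytes fell most, namely Mup19 (-5.10), Mup7 (-4.70), Mup9 (-3.21) and Mup22 (-3.04), near-identical copies among which reads are divided uncertainly, followed by Tubb2a (-0.77), Rnf213 (-0.61) and Dtx1 (-0.58).

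By camera the tissue Treg and repair list rose in liver Tconv with Penk as its 1 called member of 18 (7 when adjusted over the list alone; adjusted p = 4.07e-05, adjusted p = 0.17 with an estimated correlation). Of its members, Il10 (2.74, adjusted p = 0.0794) and Areg were not called. The Treg identity list had 1 of 14 higher, Gpr83 (0.83), and 1 lower, Foxp3 at the very low level of 0.976 against 2.26 CPM (-1.14, adjusted p = 0.0329; 8 and 1 when adjusted over the list alone; camera adjusted p = 0.004, adjusted p = 0.126 with an estimated correlation). The NKT-like list fell, with Zbtb16 the 1 called member of 15 (5 when adjusted over the list alone; camera adjusted p = 0.000137, adjusted p = 0.126 with an estimated correlation), and Klrb1c at -2.15 (adjusted p = 0.0619). Of the Th2 genes only Il17rb was called, at -1.81 (1 of 7; camera adjusted p = 0.339). Stellate and fibroblast markers rose, Col1a2 being the 1 called of 11 (4.37, 6.02 against 0.297 CPM; 4 when adjusted over the list alone; camera adjusted p = 0.000313, adjusted p = 0.126 with an estimated correlation). Camera also called 5 lists without any called member: follicular helper (adjusted p = 0.00988), activation (0.0217) and cell cycle (0.048) upward, interferon (0.0217) and NK (0.0266) downward. None held with an estimated correlation (adjusted p = 0.176, 0.564, 0.661, 0.564 and 0.176 with an estimated correlation). Gata3 (0.13), Il1rl1 (0.36), Klrg1 (-0.32), Cxcr3 (0.32), Ikzf2 (0.48), Ctla4 (0.53) and Egfr (0.13) were not called, with adjusted p between 0.163 and 0.936. Single libraries decided the count of 56: 15 genes were called without control 1, 2 without control 3, 7 without CCl4 library 4 and 17 without CCl4 library 5.

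In spleen Treg, camera called the immediate early, tissue Treg and myeloid lists upward after CCl4, with 3 of 18, 5 of 18 and 3 of 16 members called. The immediate early and tissue Treg lists lost the call with an estimated correlation (adjusted p = 0.0576 and 0.057). The stress-response gene Atf3 rose by 2.60 (adjusted p = 0.0142) and Jun by 1.27 (adjusted p = 0.0402). The adhesion gene Vcam1 rose from 3.74 ± 0.487 to 15.4 ± 3.37 CPM (n = 3 and 5; log2 fold change 2.04, SE 0.36, adjusted p = 0.00649). The histone gene Hist1h1e fell from 18.4 ± 2.15 to 8.71 ± 1.06 CPM (-1.08, SE 0.18, adjusted p = 0.00474). A total of 130 genes were higher and 72 lower, and 10.9% did not overlap (3.57% by chance). Without spleen controls 2 and 3, a choice made after seeing the data that leaves 1 control assumed to vary like the other groups, edgeR called 0 genes (1322 at an unadjusted p under 0.05; with all libraries DESeq2 called 498 and limma-voom 374). Fos in those controls was 25.2 and 22.6 CPM against 843 in control 1 and 797 to 1116 in CCl4 libraries.

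The other named rises in spleen Treg were Rasd1 (2.40), the complement gene C1qb (2.2) and Tnfaip3, a brake on NF-kB signalling (2.07). The rule also named the receptor genes Lilr4b (1.96) and Lilrb4a (1.82), Bhlhe40 (1.86) and the iron carrier Trf (1.83). Lilr4b and Lilrb4a are near-identical. Besides Hist1h1e the falls were Rcn3 (-3.30), the endolysosomal channel gene Tpcn1 (-1.15), Gdpgp1 (-1.0), Actn2 (-0.99), Slc25a27 (-0.98), Cntn1 (-0.97) and Hist1h4n (-0.95). Immediate early and heat shock genes had 3 of 18 higher (10 when adjusted over the list alone; camera adjusted p = 1.6e-14, adjusted p = 0.0576 with an estimated correlation). Tissue Treg and repair genes had 5 of 18 higher, Pparg (2.23), Nfil3 (1.24), Id2 (1.11), Ccr8 (1.09) and Gata3 (0.45, adjusted p = 0.0493; 10 when adjusted over the list alone; camera adjusted p = 1.6e-08, adjusted p = 0.057 with an estimated correlation). Activation genes had 3 of 14 higher, Nr4a2 (1.38), Tnfrsf9 (0.73) and Tnfrsf4 (0.53), which lost the list call with an estimated correlation (5 when adjusted over the list alone; camera adjusted p = 1.5e-06, adjusted p = 0.149 with an estimated correlation). Myeloid and Kupffer markers had 3 of 16 higher (7 when adjusted over the list alone; camera adjusted p = 1.6e-08, and 0.00565 with an estimated correlation). S100a8 and C1qa stood at 7.48 ± 5.85 and 5.21 ± 1.45 CPM after CCl4 against 0.0423 ± 0.0498 and 1.03 ± 0.12. Whether these transcripts, and the named rises such as Vcam1 and C1qb, came from Treg or from myeloid cells in the sort was not tested. Dendritic markers had 0 of 10 called but 7 when adjusted over the list alone (camera adjusted p = 1.21e-05, and 0.0144 with an estimated correlation).

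Smaller list changes in spleen Treg were NF-kB (2 of 15 higher, with Nfkbia at 1.06), glycolysis (0 of 16), erythroid (0 of 8) and NKT-like (1 of 15) upward, and recirculation downward (1 of 14 lower, S1pr1 at -0.47). Their camera adjusted p of 4.62e-05, 0.000162, 8.14e-05, 0.0119 and 0.000383 became adjusted p = 0.149, 0.261, 0.192, 0.274 and 0.392 with an estimated correlation. Adjusted over the list alone the counts were 5, 0, 6 and 3 higher and 1 lower. Foxp3 (0.01), Ikzf2 (-0.05), Ctla4 (0.34), Il1rl1 (0.73), Klrg1 (0.92), Il10 (1.88), Cxcr3 (0.15) and Egfr (-0.74) were not called, with adjusted p between 0.175 and 1. Besides the pair of low-Fos controls, single libraries moved the count of 202: 342 without control 1, 9 without control 2, 10 without control 3, 130 without CCl4 library 2 and 83 without CCl4 library 4.

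**Figure D4:**
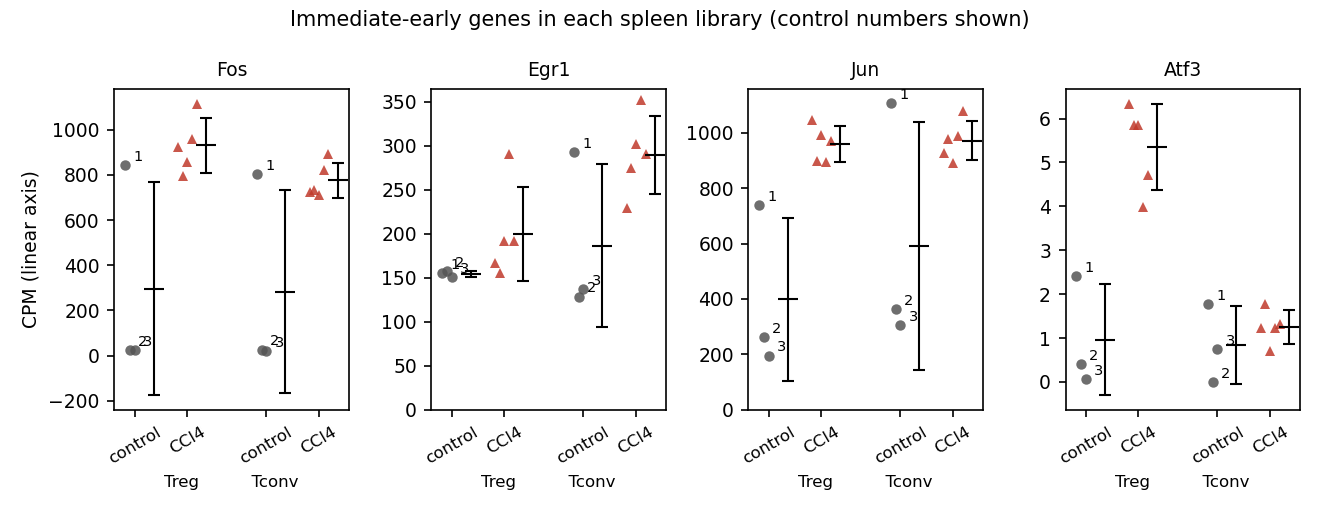
Fos, Egr1, Jun and Atf3 in CPM (y axis, linear, own range per panel) in each spleen Treg and spleen Tconv library, with mean ± SD bars; circles are the 3 controls, marked with their numbers, and triangles the 5 CCl4 libraries. Fos lay at 25.2 and 22.6 CPM in spleen Treg controls 2 and 3 and at 843 CPM in control 1.

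In spleen Tconv, edgeR called 183 genes after CCl4, and 0 in a fit of these libraries alone. The count depends on the low-Fos controls 2 and 3, so an effect of CCl4 cannot be told apart from what lowered them. Each of the 7 lists that camera called lost its call with an estimated correlation. Penk rose from 4.95 ± 1.5 to 15.6 ± 5.96 CPM (n = 3 and 5; log2 fold change 1.62, SE 0.38, adjusted p = 0.0326). The cell cycle regulator Cks2 rose from 5.95 ± 2.08 to 13.1 ± 1.95 CPM (1.12, SE 0.20, adjusted p = 0.00505). The zinc finger gene Zfp719 fell from 22.6 ± 8.43 to 8.86 ± 1.27 CPM (-1.35, SE 0.22, adjusted p = 0.00363). There were 112 genes higher and 71 lower, with 8.8% not overlapping (3.57% by chance). Further named rises were Neb (1.56), the ubiquitin ligase gene Siah2 (1.52), the phosphatase gene Dusp5 (1.43), Trib1 (1.39), Csrnp1 (1.30) and Gadd45g (1.13). Further falls were Zfp748 (-1.11), Tpcn1 (-1.04), Hist1h1e (-0.99), Rdh5 (-0.93), Vamp1 (-0.85), Zbtb5 (-0.82) and Tent5a (-0.79).

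Camera called 7 lists upward in spleen Tconv. Immediate early genes had 0 of 18 called (2 when adjusted over the list alone; adjusted p = 4.82e-09, adjusted p = 0.274 with an estimated correlation), and tissue Treg and repair 1 of 18, Penk (3 when adjusted over the list alone; 8.02e-06, adjusted p = 0.274 with an estimated correlation). Activation had 1 of 14, Tnfrsf4 at 0.69 (6 when adjusted over the list alone; 8.02e-06, adjusted p = 0.274 with an estimated correlation). Treg identity genes had 2 of 14 higher, Nt5e (0.59) and Tnfrsf18 (0.40; 8 higher and 2 lower when adjusted over the list alone; 0.0258, adjusted p = 0.274 with an estimated correlation). Oxidative phosphorylation (0.000325), myeloid (0.0265) and cell cycle (0.0463) had no called member, and their adjusted p were 0.482, 0.326 and 0.716 with an estimated correlation. Foxp3 (-0.68, adjusted p = 0.0664), Ctla4 (0.63, adjusted p = 0.0672), Gata3 (0.30), Il10 (2.05), Il1rl1 (-0.20), Klrg1 (0.45), Ikzf2 (0.07), Cxcr3 (0.29) and Egfr (0.29) were not called. Fos was 26.4 and 19.4 CPM in controls 2 and 3 against 804 in control 1. Without these controls edgeR called 0 genes (704 at an unadjusted p under 0.05; with all libraries DESeq2 called 658 and limma-voom 218). The count of 183 became 664 without control 1, 0 without control 2 (1605 at an unadjusted p under 0.05), 1 without control 3, and 116, 92 and 95 without CCl4 libraries 1, 2 and 3.

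**Figure D5:**
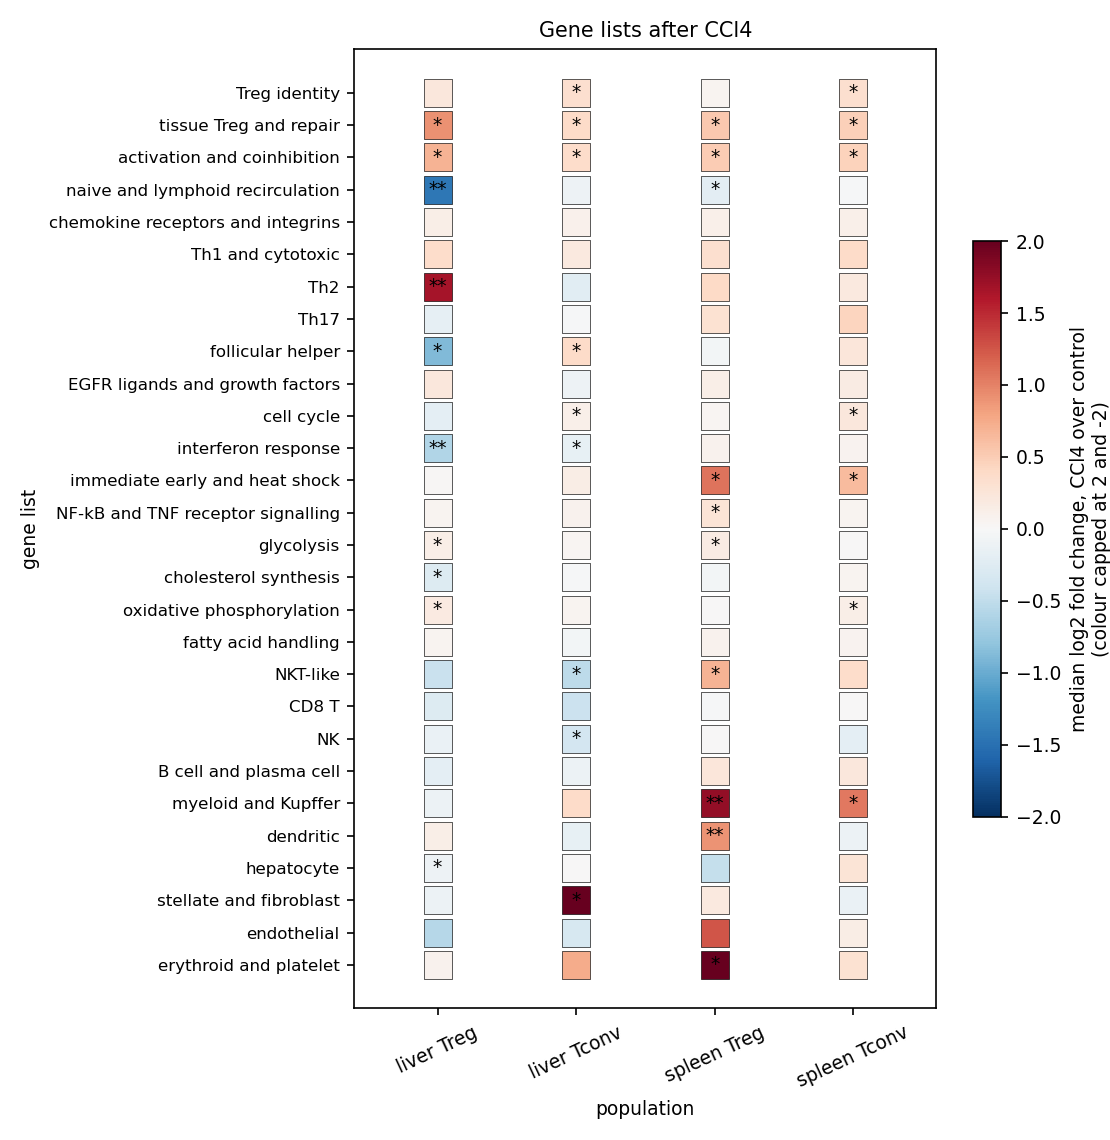
Median log2 fold change of CCl4 over control (colour, capped at 2 and -2) of each of the 28 gene lists (y axis) in each of the 4 sorted populations (x axis), from 5 CCl4 and 3 control libraries per population. A star marks a camera adjusted p under 0.05 with the preset correlation, and 2 stars the lists that also passed with an estimated correlation, among them recirculation, Th2 and interferon response in liver Treg.

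The CCl4 responses of the populations overlapped in part. Liver Treg and liver Tconv, which share no libraries but may share mice, had 13 genes higher in both (1.9 expected for independent lists) and 17 lower in both (2.3 expected), and 4 opposite. Spleen Treg and spleen Tconv, which may share mice too, had 30 higher (0.8 expected) and 23 lower (0.3 expected) in both, and 0 opposite. Hist1h1e and Tpcn1 were among these falls, and the low-Fos controls 2 and 3, on which the calls rest, stand in both comparisons. Liver Treg and spleen Treg shared 40 higher (9.8 expected) and 29 lower (5.3 expected), with 5 opposite. Across the 17159 genes, which are not independent replicates, the log2 fold changes correlated at Pearson r = 0.277 and Spearman rho = 0.246 between the liver populations and at 0.192 and 0.334 between the spleen populations. Over the 9871 genes of at least 5 CPM they were 0.535 and 0.371 in liver and 0.472 and 0.491 in spleen. Expected counts for independent lists, and a correlation of 0, leave out what libraries of the same number share. This was measured, after these values were seen, by regrouping both populations alike by number and correlating differences of mean log2 CPM (1 added). In spleen the other splits had a median r of 0.238 and a highest of 0.492 against 0.504 for the real groups, with 1 of 56 splits as large, but 6 of 56 over the 9871 genes of at least 5 CPM. In liver they had 0.169 and 0.367 against 0.351, with 2 of 56 as large (3 over those genes), and between Treg of liver and spleen 0.105 and 0.291 against 0.213, with 4 (7).

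The CCl4 effect differed between liver Treg and liver Tconv for 625 genes, 322 with a higher and 303 with a lower effect in Treg. The count was 372 in a fit of these libraries alone, where another split of the same libraries called 1270. The smallest adjusted p belonged to Evl, an actin regulator (difference of log2 fold changes -1.55, SE 0.13, adjusted p = 5.65e-09), Tcf7 (-1.50, adjusted p = 8.27e-09), Ms4a4b (-1.66), the phospholipid synthesis gene Pcyt1a (2.76) and Gpr83 (-2.54). Recirculation genes fell more in Treg (12 of 14; camera adjusted p = 2.08e-23, and 0.00974 with an estimated correlation), Th2 genes rose more (3 of 7; 7.45e-06, and 0.00974 with an estimated correlation). Fatty acid genes rose more (4 of 19; camera adjusted p = 0.0123, and 0.036 with an estimated correlation), and follicular helper genes fell more (3 of 9; 0.00027, and 0.0462 with an estimated correlation). Between liver Treg and spleen Treg 940 genes differed, 346 higher and 594 lower, led by Tcf7 (-1.45, adjusted p = 5.43e-08), Evl (-1.40), Ms4a4b (-1.31), the innate sensor gene Nod1 (-1.72) and Ehd3 (-1.20). There too the recirculation list (12 of 14 lower; camera adjusted p = 5.86e-18, and 0.0304 with an estimated correlation) and the interferon list (9 of 21 lower; 2.91e-12, and 0.0304 with an estimated correlation) fell more in liver Treg. Without spleen controls 2 and 3 this count was 330.

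In Tconv 15 genes differed in CCl4 effect between liver and spleen (5 higher, 10 lower), among them Ywhaz (-0.41, adjusted p = 0.018), Hist1h1e (1.57), Hist1h4n (1.53), Srsf6 (-0.80) and Ccrl2 (-1.68). Between spleen Treg and spleen Tconv 0 genes differed in edgeR (734 at an unadjusted p under 0.05; DESeq2 called 15 and limma-voom 0). Areg showed no called difference in its CCl4 effect in any of these 4 tests: 0.15 between the liver populations (SE 0.50, adjusted p = 0.943) and -0.70 between Treg of liver and spleen (SE 0.52, adjusted p = 0.514). It was -0.50 between Tconv (SE 0.79, adjusted p = 0.892) and 0.35 between the spleen populations (SE 0.86, adjusted p = 1). The count of 15 became 220 without spleen Tconv control 1, 0 without control 3 (1307 at an unadjusted p under 0.05) and 2 without control 2. It was 8, 5 and 3 without liver Tconv controls 1, 2 and 3, 8 and 9 without liver CCl4 libraries 4 and 5, and 5, 9 and 7 without spleen CCl4 libraries 2, 3 and 4. The count of 940 became 571 without spleen Treg control 3.

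Tissue separated Treg strongly. In liver Treg the alarmin receptor gene Il1rl1 averaged 396 ± 169 CPM against 32.8 ± 9.14 in spleen Treg (mean ± SD, n = 8 and 8; log2 fold change 3.53, SE 0.21, adjusted p = 3.92e-14). The inhibitory receptor gene Ctla4 averaged 2432 ± 176 against 546 ± 75.7 (2.18, SE 0.12, adjusted p = 8.25e-15) and Gata3 653 ± 312 against 252 ± 41.9 (1.09, SE 0.08, adjusted p = 3.93e-12). Il10 (2.95), Klrg1 (1.69), Ikzf2 (1.33), Egfr (1.81) and Cxcr3 (0.47) were higher too, and Foxp3 was not called (-0.07, adjusted p = 0.579). A total of 5167 genes were higher in liver and 5231 lower. The largest rises were Il5 (8.26), the heat shock genes Hspa1a (6.98) and Hspa1b (5.39), which are near-identical, the macrophage enzyme gene Acod1 (6.90), the hepatocyte gene Alb (6.86; 21.9 ± 32.9 CPM), Kcna4 (6.38), the endothelin receptor gene Ednrb (6.19) and Ramp3 (5.83). The largest falls were Gata1 (-3.43), Cd160 (-3.40), the iron exporter gene Slc40a1 (-3.25), Dtx1 (-3.08), Csf1r (-3.04), Dnah7a (-3.00), Nsg2 (-2.79) and Ly6c1 (-2.72).

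Of the tissue Treg and repair list 16 of 18 members were higher in liver Treg (17 when adjusted over the list alone; camera adjusted p = 2.84e-08, adjusted p = 0.15 with an estimated correlation), with Rora at 3.15, Id2 at 2.55 and Ccr8 at 2.39. Cell cycle genes were higher in 22 of 24 (camera adjusted p = 2.14e-06, adjusted p = 0.349 with an estimated correlation), Mki67 by 1.91. Chemokine receptors and integrins were higher in 17 and lower in 2 of 22 (0.000313, adjusted p = 0.312 with an estimated correlation), with Cxcr4 at 2.61, Itgav at 2.54 and Cxcr5 at -2.38. Activation (10 of 14 higher, 1 lower), Th1 (11 and 2 of 16), Th2 (5 and 0 of 7), Th17 (7 and 0 of 12), immediate early (12 and 1 of 18), NF-kB (8 and 3 of 15) and glycolysis (12 and 1 of 16) were also called upward. Called downward were recirculation (10 of 14 lower, 4 higher), interferon (17 of 21 lower, 2 higher, with Usp18 at -1.73) and oxidative phosphorylation (17 of 18 lower). Hepatocyte (16 of 16 higher) and endothelial markers (9 of 11 higher, 1 lower) were higher as well. For the immediate early genes the spleen side includes the low-Fos controls 2 and 3, which widen the difference. None of the 15 called lists held with an estimated correlation (adjusted p between 0.15 and 0.464 with an estimated correlation), and 60.6% of all genes tested were called, so the counts of members alone do not set these lists apart.

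Tconv showed a tissue difference of similar size. Ctla4 averaged 368 ± 90.1 CPM in liver against 29.6 ± 9.05 in spleen Tconv (n = 8 and 8; log2 fold change 3.65, SE 0.13, adjusted p = 5.06e-19). The receptor gene Cxcr3 averaged 284 ± 65.4 against 124 ± 26.9 (1.20, SE 0.14, adjusted p = 1.5e-08). Areg (4.96), Klrg1 (3.03), Il10 (2.74), Il1rl1 (2.39), Egfr (1.61), Ikzf2 (0.94) and Gata3 (0.36) were higher, while the trace of Foxp3 (-0.67) was lower. In all 4674 genes were higher and 4760 lower, together 55% of those tested, the share to set beside the list counts below. The named rises were all hepatocyte products at low CPM against almost none in spleen: Alb (57.5 ± 30.8 against 0.127 ± 0.178), Serpina3k (23.7), Ahsg (17.4), Pzp (16.1), Fgb (12.6), Fga (11.0), Rbp4 (10.5) and Fgg (10.4). The falls were Slc16a5 (-3.33), Gata1 (-2.37), Acvrl1 (-2.08), Mrm2 (-1.85), Glyctk (-1.75), the follicle homing receptor gene Cxcr5 (-1.72), Mettl27 (-1.68) and Lpar5 (-1.61). All 18 tissue Treg and repair genes were higher (camera adjusted p = 2.04e-09, adjusted p = 0.0732 with an estimated correlation). So were 22 of 24 cell cycle (camera adjusted p = 1.15e-10, adjusted p = 0.136 with an estimated correlation) and 15 of 18 immediate early genes (6.94e-08, adjusted p = 0.123 with an estimated correlation). For the immediate early genes the low-Fos spleen controls 2 and 3 again widen the difference. Higher too were 13 of 15 NKT-like (6.19e-05, adjusted p = 0.0742 with an estimated correlation) and 16 of 16 hepatocyte genes (1.24e-11, adjusted p = 0.0742 with an estimated correlation). Further lists were called, among them Treg identity (10 of 14 higher, 4 lower; 0.00191) and EGFR ligands (12 of 18 higher; 0.00169). No called list held with an estimated correlation. The tissue difference itself differed between Treg and Tconv for 3324 genes (1204 higher and 2120 lower in Treg), with the smallest adjusted p for Tent5a (2.91, adjusted p = 1.74e-14), Tnfsf11 (-3.02), Chd7 (1.61), Evl (-1.59) and Cd96 (-1.47). NKT-like (7 of 15 lower; camera adjusted p = 6.32e-09, and 0.0115 with an estimated correlation) and Treg identity genes (11 of 14 lower, 1 higher; 1.66e-06, and 0.00386 with an estimated correlation) had a lower liver over spleen difference in Treg than in Tconv. Areg was not called (-0.65, SE 0.47, adjusted p = 0.379). Without spleen controls 2 and 3 this count was 1731.

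Treg and Tconv of the same tissue differed by their defining programmes. In liver, Lrrc32, which anchors latent TGF-beta on Treg, averaged 886 ± 120 CPM in Treg against 4.23 ± 0.732 in Tconv (n = 8 and 8; log2 fold change 7.74, SE 0.21, adjusted p = 1.84e-22). Ikzf2 averaged 819 ± 73.4 against 19.1 ± 5.9 (5.48, SE 0.15, adjusted p = 2.29e-22). Il1rl1 (4.90), Klrg1 (4.58), Il10 (3.63), Ctla4 (2.79) and Gata3 (1.49) were higher in liver Treg, and Cxcr3 (-0.18) and Egfr (0.00) were not called. Of 17159 genes 4244 were higher in Treg and 4651 lower, together 51.8%, the share to set beside the list counts below. Besides Foxp3 and Lrrc32 the largest rises were Ky (9.94), the guanylate binding protein gene Gbp2b (8.63), Frmd5 (7.21), the carotenoid oxygenase gene Bco2 (7.15), Cep112 (7.0) and Ednrb (6.68). The largest falls were Ggt5 (-9.55), Lypd6b (-8.28), Pdlim4 (-7.21), Dapl1 (-7.13), the activating receptor gene Klrk1 (-6.77), Pde3b (-6.75), the granzyme gene Gzmk (-6.56) and Vipr1 (-6.33). Treg identity (13 of 14 higher; camera adjusted p = 3.91e-15, and 5.78e-06 with an estimated correlation) and tissue Treg genes (16 of 18 higher, 1 lower; 3.02e-10, and 0.0318 with an estimated correlation) were higher. Recirculation (14 of 14 lower; 2.11e-13, and 0.0422 with an estimated correlation), Th1 and cytotoxic (15 of 16 lower, 1 higher; 9.53e-08, and 0.0422 with an estimated correlation) and NKT-like genes (13 of 15 lower, 1 higher; 3.93e-07, and 0.0318 with an estimated correlation) were lower. The other called lists lost the call with an estimated correlation. Among them were activation (11 of 14 higher, 1 lower; 5.59e-05, then 0.249) and hepatocyte markers (11 of 16 lower; 0.00216, then 0.508).

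In spleen the same contrast called 3330 genes higher in Treg and 3475 lower, together 39.7% of those tested, the share to set beside the list counts below. The largest rises were Lrrc32 (9.20), Foxp3 (8.84), the proton pump subunit gene Atp6v0d2 (7.47), Gbp2b (7.21), Cep112 (7.15), the proteoglycan gene Sdc4 (6.86), the cytokine receptor gene Il2ra (602 ± 35.0 against 7.80 ± 1.51 CPM; 6.25, SE 0.21, adjusted p = 4.92e-20) and Slc7a10 (6.07). The falls were Pdlim4 (-7.27), Ggt5 (-6.60), Atp8b4 (-6.38), Gzmk (-5.99), Pde3b (-5.71), Vipr1 (-5.51), Lrrc75b (-5.40) and Lypd6b (-5.30). Klrg1 (5.92), Ikzf2 (5.09), Ctla4 (4.26), Il1rl1 (3.76), Areg (3.76, adjusted p = 1.5e-09), Il10 (3.42), Gata3 (0.76) and Cxcr3 (0.55) were higher, and Egfr (-0.20) was not called. Treg identity (14 of 14 higher; camera adjusted p = 4.72e-27, and 2.94e-08 with an estimated correlation) and tissue Treg genes (16 higher, 2 lower of 18; 7.71e-12, and 0.0215 with an estimated correlation) were higher. So were activation (12 of 14; 1.43e-11, and 0.0352 with an estimated correlation) and NF-kB genes (13 of 15; 5.13e-09, and 0.0352 with an estimated correlation). Recirculation genes were lower in 12 of 14 (5.34e-13, and 0.0436 with an estimated correlation). B cell markers were higher in 10 of 14 in the Treg libraries (0.000129, adjusted p = 0.0604 with an estimated correlation). Myeloid markers (4 of 16 higher) and dendritic markers (5 higher and 1 lower of 10) were also called upward. Their camera adjusted p were 0.0398 and 0.0479, and 0.231 and 0.214 with an estimated correlation. Chemokine receptors (15 higher, 3 lower of 22), cell cycle (20 of 24 higher) and Th1 genes (14 lower, 1 higher of 16) were called too. Their camera adjusted p of 2.53e-06, 2.25e-10 and 1.32e-06 became 0.0604, 0.214 and 0.0604 with an estimated correlation. Without spleen controls 2 and 3 this contrast called 4435 genes in place of 6805.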

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

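The tests on immediate early genes in the spleen controls, on NK cells in liver Tconv and on conventional cells in liver Treg, the weighing of tissue-type Treg by regrouping and by list members, and the splits of spleen Tconv at an unadjusted p, were chosen only after the result was seen; the other tests were fixed earlier.

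In liver Treg after CCl4, 13 of 14 recirculation genes fell and 9 of 18 tissue Treg genes rose. The other 9 were not called, and the tissue Treg list lost its camera call with an estimated correlation (adjusted p = 0.0886). Of the recirculation genes 12 fell more there than in spleen Treg. Fewer conventional T cells among the sorted Treg would need their genes to be present in control liver Treg. Of 89 genes far above Treg in spleen Tconv, the lowest decile stayed under 0.0284 of its liver Tconv level there and the median share was 0.124, where the fall of the naive list needs a median of 0.231 (quartiles 0.101 and 0.363). This argues against admixed cells like liver Tconv, although the test first planned, a median log2 fold change of -0.78 over 100 such genes, gave neither outcome, and admixed cells of another kind are not covered. A larger share of tissue-type Treg stays open. The planned test, a correlation across 9871 genes between the CCl4 effect and the liver over spleen difference in Treg, gave 0.008, below its bound, but both contrasts hold the same liver Treg libraries. On mean log2 CPM it was 0.184, within the -0.38 to 0.328 of the 55 other splits of those libraries, so it decides nothing. Across the 32 members of both lists it was 0.783, but on mean log2 CPM the other splits reached 0.82 against 0.769, with 8 of 56 as large, so this decides nothing either. Against a larger share of cells like the liver average, Ccr7 (-1.56 after CCl4, 0.98 for liver over spleen), S1pr1 (-1.32 and 0.27) and Klf2 (-0.83 and 0.57) fell while being higher in liver. A direct effect of CCl4 was not tested.

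Immediate early genes were low in spleen controls 2 and 3 in both cell types, so they move with the CCl4 comparisons of the spleen. The low level was not seen in the liver samples of the same numbers. The median log2 difference of controls 2 and 3 from control 1 was -0.15 in liver Treg and -0.16 in liver Tconv. In spleen Treg and Tconv it was -1.38 and -1.10. This does not exclude a state shared with the liver. The labels do not say that numbers mark the same mice. In a contrast that holds these spleen controls, 12 of 18 members were higher in liver than in spleen Treg. Handling of the spleens numbered 2 and 3 stays open: these were the lowest 2 of 8 libraries in both populations for 11 of 18 members, but this restates the pattern and favours handling over no other cause of 2 low spleens. The labels record no handling. CCl4 treatment cannot be told apart from it either: control 1 lay at or above the lowest CCl4 library for 10 of 18 members in spleen Treg and 17 in spleen Tconv, but this is 1 control per population.

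NKT-like markers fell as a list in liver Tconv by camera (adjusted p = 0.000137), with Zbtb16 the 1 called member of 15 and the call lost with an estimated correlation (adjusted p = 0.126). Fewer NKT cells with the invariant receptor are a candidate explanation: Trav11 and Trav11d together went from 26.8 ± 13.6 to 6.18 ± 2.14 CPM (here without TMM, as for the other levels of this paragraph; log2 ratio -2.12, two-sided exact permutation p = 0.0179, the smallest possible for n = 3 and 5), while all Trav segments together went from 353 ± 13.6 to 469 ± 66.8 CPM (0.41, exact permutation p = 0.0357). Fewer NK cells stay open, although the gate on TCRb would remove them. Ncr1 in the controls was 0.023 of the level of Klrb1c (0.174 against 7.56 CPM), which is near the floor and decides nothing. The NK list was lower by camera (adjusted p = 0.0266, adjusted p = 0.176 with an estimated correlation) with no member called. Whether the cells were fewer or carried fewer transcripts was not tested.

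Tests of the difference in CCl4 effect itself called 625 genes between liver Treg and liver Tconv, 940 between liver and spleen Treg and 15 between liver and spleen Tconv. For the 15 the splits below could not exclude chance. The tissue difference differed between Treg and Tconv for 3324 genes. Over the depth and the focus genes, 4 of 48 groups of CCl4 libraries had 1 library far from the rest, where chance gives about 1 in 20 groups. Il10 in liver Tconv after CCl4 was 70.4 CPM in library 4 against 7.37 to 24.9 in the others (gap over range 0.721), and Il10 in spleen Tconv after CCl4 was 11.1 in library 4 against 0.498 to 2.3 (0.831). Klrg1 in spleen Tconv after CCl4 was 5.48 in library 1 against 0.523 to 1.24 (0.856), and Egfr was 1.05 in library 3 against 0.323 to 0.494 (0.763).

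Chance was weighed by regrouping the libraries of each comparison in a fit of those libraries alone, over all 56 splits for the CCl4 comparisons and 100 splits for the others. The splits treat the libraries as independent, which the labels do not establish. On that footing chance can be excluded for liver Treg (2060 genes, highest other split 1) and spleen Treg (189, highest other 2). The spleen Treg count rests on the low-Fos controls 2 and 3, so an effect of CCl4 cannot be told apart from what lowered them. For liver Tconv chance can be excluded only by the share of splits (7 genes, 2 of 56 as large). The split with CCl4 libraries 2, 3 and 4 in place of the controls called 14, and in the fit of all libraries the count of 56 became 2 without control 3, so this exclusion is not firm. It can be excluded for the contrasts of tissue in Treg (10315, 6386) and Tconv (8918, 5996) and of cell type in liver (8368, 5082) and spleen (6881, 4044). The real groups gave 372 genes for the difference of CCl4 effects between liver Treg and liver Tconv (2 splits as large). They gave 985 between liver and spleen Treg (highest other 612) and 3324 for the difference of tissue differences (highest other 159). These splits shuffled treatment within each population, or tissue within cell type and treatment. They thus weigh against no effect in either group, and cannot tell unequal effects from equal ones. For liver Treg against liver Tconv another split called 1270, several times the real count. That split kept all 3 liver Treg controls and 1 of the liver Tconv controls, so it holds the real grouping of liver Treg. Every other split that was drawn called 5 or fewer. The count of 372 thus shows an effect in liver Treg more firmly than a difference from liver Tconv. For spleen Tconv edgeR called 0 genes in this fit (highest other 5; DESeq2 658 and limma-voom 218 in the fit of all libraries), so all 56 splits are as large by construction and say nothing about chance. By the count at an unadjusted p under 0.05, a measure chosen after that result, no other split was as large (2306, highest other 2152). The margin is small, so chance is not firmly excluded. The split with 2152 kept controls 2 and 3 and took CCl4 library 4 for control 1, so the low-Fos controls carry much of this count. Chance cannot be excluded for the difference between liver and spleen Tconv (1, highest other 9, 7 splits as large) or for that between spleen Treg and Tconv (1, highest other 3, 6 splits as large).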

How the results depend on the processing

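The alternative without the low-Fos spleen controls was chosen after seeing the data; all other alternatives and their tests were fixed earlier. The contrasts of tissue and of cell type kept their direction for nearly every named gene: of the called genes under all alternatives together, 0 of 896 values in Treg and 2 of 644 in Tconv were no longer past the threshold for tissue, and 0 of 575 in liver and 1 of 600 in spleen for cell type. For CCl4 these were 12 of 829 in liver Treg, 146 of 335 in liver Tconv, 196 of 522 in spleen Treg and 128 of 322 in spleen Tconv. An estimated correlation ended the call of 7 of 10 lists in liver Treg, 9 of 9 in liver Tconv, 8 of 10 in spleen Treg and 7 of 7 in spleen Tconv. Fry, which asks whether list members change at all rather than more than other genes, kept some of these calls. In liver Treg the fry adjusted p was 1.14e-05 for tissue Treg, 0.00317 for activation and 0.000289 for cholesterol synthesis, but 0.0528 for glycolysis. In liver Tconv it was 0.0341 for tissue Treg and 0.0183 for NKT-like, but 0.309 for activation and 0.228 for interferon. With 3 controls, leaving out 1 moved counts strongly. At this depth genes near the floor, such as Egfr, give no firm direction for CCl4 and cell type, though Egfr was called higher in liver in Treg and in Tconv. The cause was not tested for any change given here, except that fewer genes or fewer libraries were tested where the alternative says so. The labels do not say that sample numbers pair the libraries. Within a treatment, in 38 of 48 matches of a library to another population its own number matched best, a hint from the data. A control and a CCl4 library of the same number and population showed none (median correlation -0.008 in liver Treg, -0.041 in liver Tconv, -0.045 in spleen Treg and -0.063 in spleen Tconv), so for the CCl4 comparisons the block by number is given only because it was planned. Named genes under 5 CPM have no value under that filter, and Fos and Tnfaip3 in spleen have none in DESeq2.

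Size factors of DESeq2 gave Areg 1.58 in spleen Treg (adjusted p = 0.047, with a range over alternatives from 0.00177 to 0.836), and Egfr 0.01 for Treg against Tconv in liver. No filter gave 24 genes in liver Tconv, 101 in spleen Tconv and Egfr 0 for Treg against Tconv in liver. A mean of at least 5 CPM gave 326 genes in spleen Tconv, 6875 for tissue in Treg, Areg 1.54 in spleen Treg, Foxp3 -0.01 in spleen Treg and 0.09 for tissue in Treg. Length offsets gave Areg 1.62 in spleen Treg, Foxp3 -0.03 and Egfr 1.35 in liver Treg, and Egfr -1.34 and Ikzf2 -0.02 in spleen Tconv. As deposited TPM, which divide by length, Areg stood at 116 and 204 in control and CCl4 liver Treg, 12.1 and 19.2 in liver Tconv and 12.6 in CCl4 spleen Treg. Over the 9871 genes of at least 5 CPM, agreement was 0.535 between liver Treg and liver Tconv, 0.12 between liver Treg and spleen Treg, -0.014 between liver Tconv and spleen Treg, 0.131 between liver Tconv and spleen Tconv, and 0.472 between spleen Treg and spleen Tconv.

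Without the low-Fos spleen controls the counts were 26 in liver Tconv, 0 in spleen Treg and 0 in spleen Tconv (1322 and 704 at an unadjusted p under 0.05 in edgeR; DESeq2 called 498 and 658 and limma-voom 374 and 218 with all libraries), 4435 for cell type in spleen. They were 330, 5 and 1731 for the differences of effects in Treg, in Tconv and of tissue. Areg was then 0.86 in liver Treg (adjusted p = 0.0253, range over alternatives 0.000746 to 0.351), 0.57 in spleen Treg (adjusted p = 0.836, range 0.00177 to 0.836) and 0.05 in spleen Tconv (adjusted p = 1, range 0.0674 to 1), and its differences of effects were 0.29 in Treg and 0.66 in Tconv. Foxp3 was 0.03 for tissue in Treg, Fos -0.05 in spleen Tconv, Egfr 0 for Treg against Tconv in liver, and the immediate early list had an adjusted p of 0.789 in spleen Tconv.

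A fit of the libraries compared alone gave 7 genes in liver Tconv, 0 in spleen Tconv (2306 at an unadjusted p under 0.05 in edgeR), and 372, 1 and 1 for the differences in liver, in Tconv and in spleen. It gave Areg 0.85 in liver Treg, Foxp3 0 in spleen Treg and Egfr 0.02 for Treg against Tconv in liver. With limma-voom the counts were 156 in liver Tconv and 374 in spleen Treg. Areg was 0.87 in liver Treg, 1.90 in spleen Treg and -0.58 for the difference in spleen. In liver Treg Egfr was 0.07 and Alb -1.30. DESeq2 gave 273, 498 and 658 genes in liver Tconv, spleen Treg and spleen Tconv, 951, 1473, 157 and 15 for the 4 differences of CCl4 effects, and Egfr 0.01 for Treg against Tconv in liver. The block gave 933, 0, 12 and 0 genes in liver Treg, liver Tconv, spleen Treg and spleen Tconv (884 and 2113 at an unadjusted p under 0.05 in edgeR for the Tconv of liver and spleen), and 363, 5 and 1 for the differences in liver, in Tconv and in spleen. It gave Areg -0.09 for the difference in spleen, Alb -0.13 in liver Treg, Foxp3 -0.06 in spleen Treg, Ikzf2 -0.02 in spleen Tconv, Egfr 0.04 for Treg against Tconv in liver, and an adjusted p of 0.75 for the cell cycle list in liver Tconv.

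Leaving out 1 library gave counts of 1779 to 2533 in liver Treg, 2 to 69 in liver Tconv, 9 to 342 in spleen Treg, 0 to 664 in spleen Tconv, 9753 to 10359 and 8778 to 9387 for tissue in Treg and Tconv, and 8350 to 8913 and 6226 to 6700 for cell type in liver and spleen. For the differences it gave 463 to 672 in liver, 571 to 984 in Treg, 0 to 220 in Tconv, 0 to 2 in spleen and 2906 to 3444 for tissue. Areg ran from 0.64 to 1.07 in liver Treg, 0.56 to 1.03 in liver Tconv, 1.20 to 2.42 in spleen Treg (called only without control 1, adjusted p = 0.00177) and 0.54 to 3.80 in spleen Tconv. It ran from 4.12 to 4.73 and 4.62 to 6.25 for tissue, 3.00 to 3.26 and 3.33 to 5.05 for cell type, and for the differences -0.16 to 0.36 in liver, -1.55 to -0.33 in Treg, -3.09 to 0.17 in Tconv, -2.24 to 1.20 in spleen and -1.94 to -0.23 for tissue (-1.94 without spleen Tconv control 1, adjusted p = 0.0433). In liver Treg Egfr ran from -0.43 to 0.22, Cxcr3 from -0.24 to 0.10 and Alb from -1.73 to 0.93. In liver Tconv Klrg1 ran from -0.74 to 0.51, Egfr from -0.17 to 0.43 and the adjusted p of the cell cycle list from 0.00126 to 0.399. In spleen Treg Foxp3 ran from -0.08 to 0.09 and Ikzf2 from -0.12 to 0.01. In spleen Tconv Klrg1 ran from -0.48 to 0.79, Egfr from -0.14 to 0.42 and Ikzf2 from -0.06 to 0.17. Egfr ran from -0.15 to 0.17 and from -0.30 to 0.01 for cell type in liver and spleen.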

Other observations

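No tests were added in this part; its genes were chosen only after their values were seen. Penk, the opioid precursor gene, rose in 3 populations and stood at similar levels in the control libraries of both Treg populations. It went from 63.9 ± 9.72 to 188 ± 66.4 CPM in liver Treg (n = 3 and 5; log2 fold change 1.56, SE 0.35, adjusted p = 0.00244), from 5.43 ± 0.441 to 35.6 ± 19.5 in liver Tconv and from 4.95 ± 1.5 to 15.6 ± 5.96 in spleen Tconv. In spleen Treg it was 64.3 ± 11.2 and 92.6 ± 29.2 CPM and was not called (0.53, SE 0.34, adjusted p = 0.527). Cyp11a1 after CCl4 stood at 56.5 CPM in liver Treg, against 0.573 in liver Tconv and 0.339 in spleen Tconv, and it rose in spleen Treg from 0.476 ± 0.151 to 1.51 ± 0.443 CPM (1.62, adjusted p = 0.0226).

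Il17rb, a receptor chain for an epithelial alarmin, moved in opposite directions in the liver populations. It rose in Treg from 10.9 ± 0.232 to 34.8 ± 12.9 CPM and fell in Tconv from 8.40 ± 3.25 to 2.40 ± 1.11. Il5 rose from 1.63 to 19.2 CPM in liver Treg and was 5.28 ± 3.38 and 2.52 ± 0.85 CPM in control and CCl4 liver Tconv. Afp, known as a fetal serum protein, rose in liver Treg from 1.10 to 10.5 CPM, while spleen Tconv held 25.7 and 22.7 CPM. Hist1h1e and Tpcn1 fell in both spleen populations (Hist1h1e -1.08 and -0.99, Tpcn1 -1.15 and -1.04 in Treg and Tconv) and were not called in liver Treg (0.26, adjusted p = 0.41, and -0.53, adjusted p = 0.0873). Each spleen call in this part was lost without spleen controls 2 and 3, where edgeR called 0 genes in spleen Treg and spleen Tconv (1322 and 704 at an unadjusted p under 0.05; with all libraries DESeq2 called 498 and 658 and limma-voom 374 and 218).

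Mup1, a hepatocyte product whose near-identical copies divide reads uncertainly, fell from 12.5 to 1.42 CPM in liver Treg and was 64.0 ± 15.4 and 11.7 ± 7.59 in control and CCl4 liver Tconv. Pancreatic enzymes stood apart in control library 1 of liver Treg, with Amy2a5 at 422.5, Cela2a at 232.8, Pnlip at 195.4 and Prss2 at 138.7 CPM; control library 1 of liver Tconv had 32.2, 5.72, 8.24 and 5.76 CPM of the same genes.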
